A study of Glycine max with 36 samples.

How the data were processed

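Small RNA libraries of soybean (Glycine max) were analysed from the tables deposited by the authors: 36 libraries of total RNA, 14 from immature seed coats, 7 from seedling cotyledons of 7 stages, 6 from shoot tips, 3 from vegetative buds, 2 from embryo axes and 1 each from dry seed coat, dry cotyledon, immature cotyledon and leaf. Williams, Clark 63 and Clark carry the i-i allele of the I locus, Richland carries I, and T157 and Williams 44 carry i. Per the labels, seed parts were separated by hand and seeds were staged by fresh weight. Libraries were made with either of 2 small RNA kits on either of 2 sequencer models, and the labels do not say which was used for which library, so no kit or instrument batch could be fitted.

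Values were used as deposited in 2 units. The strand table holds, per the file headers, raw counts of read hits for 86256 transcript models, split into total and unique hits on the sense and the antisense strand. The CHS table holds, per the file headers, total counts of CHS7 and CHS8 and their RPM, which the authors computed by dividing by the reads of each library. The counts of both tables were checked to be equal for CHS7 and for CHS8 in all 36 libraries, and the RPM to equal count over reads in all 36. Reads were aligned with Bowtie 1 per the submitters' processing notes. Mismatches, read sizes, trimming and the rule for a unique hit are not given in the sources used here. Hits of all read lengths are pooled, so small interfering RNAs, microRNAs and fragments of messenger RNA enter the same count.

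Reads were not followed between genes here. Counts of 6047 genes equal those of another gene in all libraries, so counts of called genes were not taken as counts of separate small RNA sources, and values of single paralogs, among them the 20 genes matched to Arabidopsis CHS, are uncertain. Unique hits made up 92.6% of total hits and equalled them for 88.4% of genes, and so do not separate paralogs.

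Each gene was represented by the transcript marked as its lowest splice form, which gave 52872 genes, of which 44168 had a hit in some library and 9437 had no description. Sense and antisense total hits were summed. The reads per library ranged from 9.50 to 58.5 M (1e+06 reads, median 20.4) and gene hits from 5.74 to 85.3 M (median 24.6) apart from the stage 2 seedling cotyledon library, which had 0.965 M from 20.0 M reads and hits on 1122 genes, against 18760 to 34200 genes in the others. The 20 most abundant genes took 59.0 to 92.9% of hits per library. At these depths 3 counts correspond to 0.0584 to 0.259 RPM in the seed coat libraries. Intervals on ratios and shares of counts cover counting error only, and libraries of a group varied far more. Sums of squared deviations over their counting expectation were 21.0 to 384 per degree of freedom. They were 21.0 to 90.2 for pairs of like stage (Richland, T157 and standard tips). The other pairs also differ in stage, such as the Williams seed coats of 100 to 200 and 200 to 300 mg (384).

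Gene comparisons were made with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15) in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes as the threshold. They were Richland against T157 at 5 to 6 mg (3 against 3), Williams immature seed coats of 100 to 500 mg against seedling cotyledons (3 against 7), the linear trend over the 7 cotyledon stages, and, in a single model of 9 Clark libraries with isoline and tissue terms, vegetative buds against adult shoot tips (3 against 4), five-foliate against standard and glabrous against standard (3 against 3). The 2 tip libraries from 1-month plants formed their own tissue level. Libraries of a group in the Williams comparison differ in stage, so stage is part of their spread. The summed CHS7 and CHS8 RPM were compared on log2(RPM + 1) with two-sided exact permutation tests in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9) for 3 contrasts. The leaf, dry cotyledon, immature cotyledon and embryo axis libraries entered these contrasts only, and the dry seed coat is given as a value.

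The comparisons, the main tests, the first set of alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. Named were CHS7 and CHS8, the 8 genes with the largest change in each direction among called genes with a mean of at least 5 CPM and, for comparisons of 2 groups, no overlap between groups, and the 2 genes with the smallest p in each list; the texts give most of these, and other genes are named only where the texts say that they were chosen later or where a list had few calls. CHS7 and CHS8 are named as in the authors' table, other genes by Glyma identifier and the description deposited with the table. The 14 lists, chosen by words in those descriptions, were flavonoid pathway without CHS, chalcone synthase, resistance genes, pentatricopeptide, MYB, auxin signalling, RNA silencing, growth factor targets of microRNAs, laccase and copper proteins, photosynthesis, seed storage, ribosomal protein, histone and transposon-related. Matching by words brought in genes of other function: 203 of the 354 transposon-related genes are Integrase-type DNA-binding factors, 29 of the 146 growth factor targets are TCP-1 chaperonins, 153 of the 493 seed storage genes are Bifunctional inhibitor or lipid-transfer proteins, and 2 of the 25 chalcone synthase genes are ketoacyl-ACP synthases. Photosynthesis and seed storage were also chosen as markers of tissue carried over in dissection. Of the 493 seed storage genes, 156 are described as late embryogenesis abundant, so that list marks cotyledon and embryo only loosely. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation.

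Tested on simulated data with 200 changed genes per comparison, changes of 1, 2 and 3 log2 were recovered for 16.2, 80.3 and 98.2% of genes in Richland against T157, 0, 10.0 and 47.1% in Williams seed coat against cotyledon, 2.86, 44.9 and 90.2% in buds against tips, 1.45, 32.1 and 66.7% in five-foliate and 0, 47.3 and 81.2% in glabrous against standard; trends of 0.5 and 1 log2 per stage were recovered for 15.0 and 88.0%. Of all simulated calls, 2.78 to 11.4% were on unchanged genes. The adjusted threshold is stricter when fewer genes differ. The simulated Williams seed coat against cotyledon called 44 genes in all, against 7908 in the data. Its recovery may therefore understate that of the real comparison.

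Alternatives were DESeq2 size factors, no TMM factors, no low-count filter, the DESeq2 1.42.0 Wald test, unique hits, antisense or sense hits alone, a replicate block for Richland and T157, each library left out in turn and, for the CHS sums, pseudocounts of 0.1 and 10, the linear scale, gene hits as the divisor, unique hits and restricted sets of lines. Merging genes with identical counts, summing the 20 CHS genes and leaving out the stage 2 library in list tests were added after the data had been seen. Hits within 5% of each other, by summed absolute difference over summed counts, defined groups of genes with near-equal counts. No genome coordinates were used here.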

Results

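In soybean, the dominant I and i-i alleles of the I locus keep the seed coat yellow, with i-i leaving pigment in the hilum, and the recessive i allele gives a pigmented coat. Chalcone synthase (CHS) makes the entry step of flavonoid and anthocyanin synthesis, and the series asks in which tissues small RNAs of the CHS genes occur. Small RNA hits on CHS7 (Glyma.01G228700), CHS8 (Glyma.11G011500) and 52872 annotated genes in all were compared between 36 libraries of seed coats, cotyledons, embryo axes, leaf, vegetative buds and shoot tips.

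Small RNAs of CHS7 and CHS8 were abundant in immature seed coats carrying i-i and scarce in the other i-i tissues. Summed CHS7 and CHS8 hits were 5100 ± 4086 RPM (hits scaled by library reads, mean ± SD, range 1024 to 11518) in the seed coats, n = 5 libraries of Williams, Clark 63 and a Clark isoline, UC413, with genotype mi, a minute hilum and a defective coat (Clark mi below). They were 5.87 ± 3.38 RPM (range 0 to 11.5, n = 21) in the other tissues. By tissue these were 11.5 RPM in immature cotyledon (n = 1), 9.21 RPM in dry cotyledon (n = 1), 7.26 ± 0.875 RPM in embryo axes (n = 2). Next came 3.68 ± 2.72 RPM in seedling cotyledons (n = 7), 1.21 RPM in leaf (n = 1), 6.96 ± 1.03 RPM in vegetative buds (n = 3) and 6.71 ± 3.80 RPM in shoot tips (n = 6). The lowest seed coat library was 89.2 times the highest library of another tissue. The dry mature Williams seed coat, which entered no test, held 5295 RPM. CHS hits came from both strands of the transcripts: the sense share was 63.8 to 70.1% in the 3 Williams seed coats, 65.4% in Clark 63, 65.2% in Clark mi and 71.8% in the dry seed coat. Mean log2(RPM + 1) was 9.34 higher in the i-i immature seed coats (two-sided exact permutation test, p = 1.52e-05, the smallest value that the 65780 arrangements allow; Benjamini-Hochberg adjusted p = 4.56e-05 over the 3 CHS comparisons).

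Among immature seed coats, CHS7 and CHS8 small RNAs separated the I and i-i genotypes from the i genotypes. The sum was 3107 ± 3755 RPM with I or i-i (range 170 to 11518, n = 9) and 37.2 ± 46.9 RPM with i (range 9.84 to 121, n = 5). By line, Richland (I) held 287 ± 111 RPM at 5 to 6 mg seed weight (n = 3) and 1604 RPM at 10 to 25 mg (n = 1), Clark 63 (i-i) 6500 RPM and Clark mi (i-i) 3109 RPM. T157 (i), whose coat is imperfect black, held 13.5 ± 3.46 RPM at 5 to 6 mg (n = 3) and 25.1 RPM at 10 to 25 mg (n = 1). The black-coated Williams 44 (i) held 121 RPM, of which 99.9% was sense, against 72.9 to 92.5% sense in the 5 to 6 mg T157 libraries and 63.8 to 81.7% sense in the 9 silencing seed coats. Mean log2(RPM + 1) differed by 5.86 (two-sided exact permutation test, p = 0.0005, the smallest that the 2002 arrangements allow; adjusted p = 0.000749). The groups also differ in cultivar and seed weight, the lowest I or i-i library was only 1.41 times the highest i library, and on the linear RPM scale the difference of 3070 RPM gave exact p = 0.0619.

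**Figure D1:**
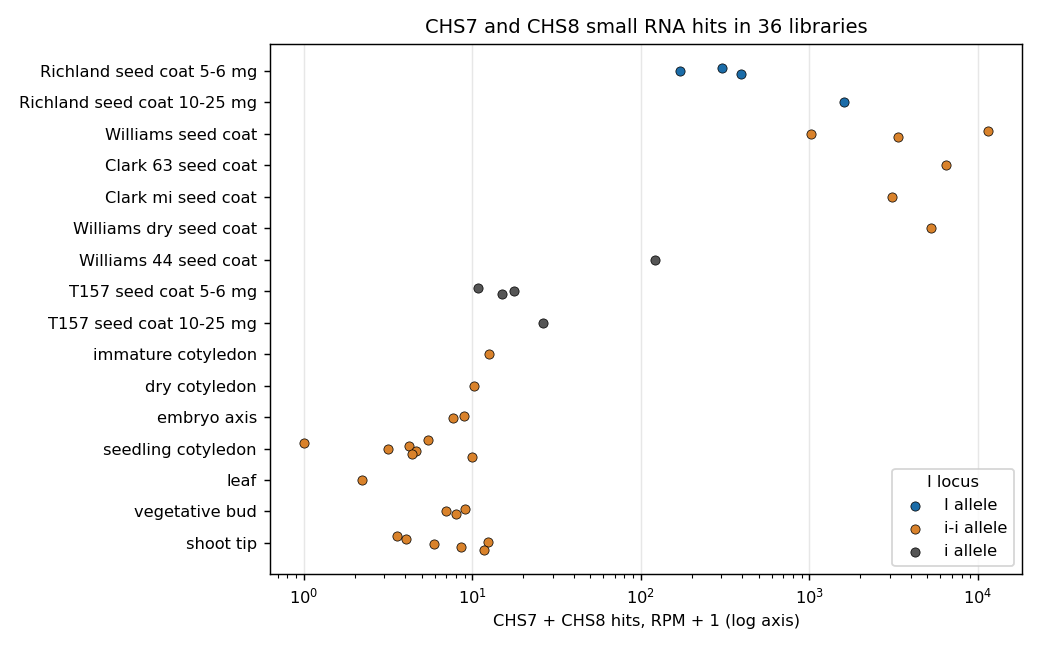
Summed CHS7 and CHS8 hits of each of the 36 libraries in RPM + 1 on a log axis, 1 point per library, colored by I-locus allele. The 5 i-i immature seed coats lie between 1024 and 11518 RPM and the 21 other i-i libraries, the dry seed coat apart, at or under 11.5 RPM.

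Richland seed coats held more small RNAs of the CHS family than T157 seed coats of the same weight, 5 to 6 mg. Hits on CHS7 were higher in Richland by 4.69 ± 0.42 log2 (fold change ± standard error, 3 against 3 libraries), at 266 ± 66.4 against 10.3 ± 0.737 CPM (hits scaled by gene hits, mean ± SD). Hits on CHS8 were higher by 4.75 ± 0.42 (261 ± 66.4 against 9.70 ± 0.953 CPM). The chromosome 8 members Glyma.08G110300 and Glyma.08G110460 rose by 4.54, Glyma.08G110801 by 4.44 and Glyma.08G109400, Glyma.08G110420 and Glyma.08G110901 by 4.41, the last 3 with identical counts in every library. Of the 21 tested members of the chalcone synthase list, 19 rose and none fell (19 when adjusted over the list alone). The list as a whole moved up, with adjusted p = 1.1e-194 at a preset correlation of 0.01 between genes and adjusted p = 0.0157 with an estimated correlation. The summed CHS7 and CHS8 RPM differed by 4.26 in mean log2(RPM + 1), 19.1-fold, with exact permutation p = 0.1, the smallest possible for 3 against 3.

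In all, 121 of 10761 tested genes differed between Richland and T157, 70 higher and 51 lower in Richland. Outside the CHS family, the pentatricopeptide repeat genes Glyma.05G072500 and Glyma.19G055700, of a class that edits and processes organelle RNA, each had 86 antisense hits in Richland and 0 in T157, at least 35.2-fold higher by a floor of 3 counts over the group. The MYB-like gene Glyma.01G038600 rose by 2.06 ± 0.49. The largest decreases in Richland with a mean of at least 5 CPM were near −2.7: the ABC transporter gene PDR11 (Glyma.02G159900, −2.76 ± 0.43), the receptor kinase gene TMK1 (Glyma.10G081300, −2.72) and Glyma.13G079800 (DUF740 domain, −2.72). Beside them fell a glucose-1-phosphate adenylyltransferase gene of starch synthesis (Glyma.11G223500, −2.72), the malate transporter genes Glyma.08G260200 (−2.69) and Glyma.02G097700 (−2.67), the leucine-rich repeat kinase gene Glyma.02G197000 (−2.68) and Glyma.08G366000, which has no description (−2.69). Glyma.13G079800 and Glyma.08G366000 had almost equal means (5.70 and 5.90 CPM in Richland, 37.8 and 38.2 in T157). The others named here as lower also nearly matched each other, at 2.51 to 2.61 CPM in Richland and 16.7 to 17.2 in T157. These genes may share reads and were not taken as separate decreases. Many of the called genes had near-equal counts: by counts within 5% of each other over all 6 libraries, the 51 lower genes formed 22 groups and the 70 higher genes 41. Among the other lists, 2 pentatricopeptide genes rose and 2, Glyma.13G060751 and Glyma.13G060802 (−1.58 each), fell. Also, 1 MYB gene rose and ribosomal protein L20 (Glyma.12G232100) fell by 1.41 on the log2 scale. No tested member of the flavonoid pathway (7), resistance gene (311), auxin (51), RNA silencing (18), growth factor target (65), laccase (22), photosynthesis (24), seed storage (63), histone (20) or transposon (105) list was called, over all genes or adjusted over the list alone. The flavanone 3-hydroxylase genes Glyma.02G048400 (0.79 ± 0.39) and Glyma.16G128700 (0.81 ± 0.39) and the dicer-like 4 gene Glyma.13G156500 (−0.80 ± 0.46) did not pass. The flavonoid list (up, adjusted p = 0.0399) and the growth factor target list (down, adjusted p = 0.00827) passed at the preset correlation alone, each with adjusted p = 0.25 with an estimated correlation.

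The groups of 111 of the 121 called genes did not overlap, as 11.7% of all tested genes did and 10% would by chance. Fewer genes were called from the antisense hits alone (75) or the sense hits alone (66), and 75 when genes with identical counts were merged. The labels do not say that replicates are separate plants, so all p-values measure only the spread between these libraries.

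**Figure D2:**
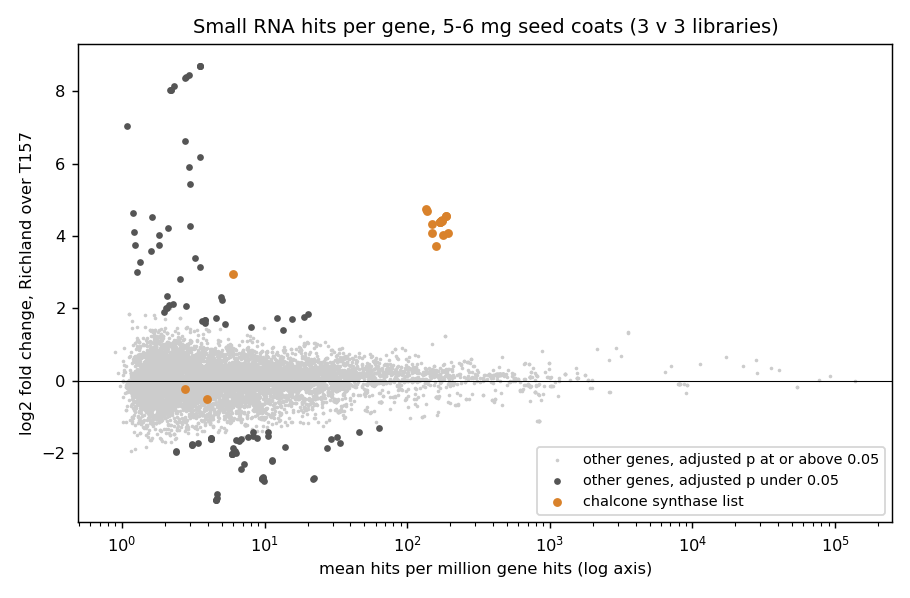
Log2 fold change of Richland over T157 (3 against 3 libraries of 5 to 6 mg seed coats) against mean CPM on a log axis, 1 point per gene. The chalcone synthase list (orange) stands apart from genes of like abundance, 19 of its 21 members having risen.

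In the Williams cultivar, immature seed coats and seedling cotyledons differed for 7908 of 16669 genes, 4078 higher and 3830 lower in the seed coat. CHS7 and CHS8 hits were higher by 8.80 ± 1.05 log2 each (3 against 7 libraries; CHS7 1063 ± 830 against 2.28 ± 1.54 CPM), and 19 of 21 chalcone synthase list members rose with none lower (19 adjusted over the list alone). Sense hits on 3 glycine-rich protein genes were among the largest differences, while of 16 tested genes so described, tallied after the values were seen, 5 rose and 3 fell. The 5 risen genes formed 4 groups of near-equal counts. With counts pooled over each group, Glyma.20G011400 (199772 against 0 counts) was at least 85112-fold higher and Glyma.07G176200 (139159 against 0) at least 59288-fold higher by the floor of 3 counts over the group. Glyma.07G176000 rose by 14.63 ± 1.67 log2. These 3 genes varied widely between the Williams libraries (856 ± 926, 590 ± 649 and 855 ± 924 CPM), so the pooled folds need not hold for each library. MYB transcription factor genes stood beside them. MYB93 (Glyma.06G103300, 46730 against 0 counts) was at least 19909-fold higher. The MYB5 homologs Glyma.05G061900 and Glyma.17G143600, of a family regulating flavonoid and seed coat development in Arabidopsis, had 7774 and 7629 counts against 2 each, ratios of 4968 (95% counting interval 1375 to 41031) and 4875 (1349 to 40266). Seed coat CPM was 239 ± 188 for MYB93 and 44.4 ± 69.8 and 43.6 ± 68.8 for the MYB5 homologs. The MYB5 homologs nearly matched each other in counts, as did Glyma.20G011400 and Glyma.07G176000 (199772 and 199406 in the seed coats). Each pair may share reads and was not taken as separate increases.

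MYB15 (Glyma.10G165800) rose by 9.21 ± 1.07, the homeodomain-like gene Glyma.13G136300 had 2008 counts against 1 (ratio 2567, interval 460 to 101421) and the undescribed Glyma.11G144450 3134 against 3 (ratio 1335, interval 456 to 6478). Lower in the seed coat were the MLP423 genes Glyma.07G243500 and Glyma.17G030400 (−10.36 ± 1.86 each) and Glyma.07G243651 (−8.59 ± 1.73) and ribosomal protein L32 (Glyma.18G193100, −9.21 ± 1.61). So were the adaptin gene Glyma.11G095501 (−7.26 ± 1.23), the undescribed Glyma.09G008000 (−6.97 ± 1.37), the XS domain gene Glyma.05G198500 (−6.93 ± 1.26) and the resistance gene Glyma.15G160900 (−6.25 ± 1.91). Glyma.15G160900 had 42.8 ± 103.9 CPM in cotyledons from 781 counts, against 50.7 ± 22.1 CPM from 7897 for Glyma.05G198500. So high a mean from so few counts rests largely on the stage 2 library, which had the fewest hits. Its fold therefore need not hold for the other stages. The MLP423 genes also had SDs above their cotyledon means (32.3 ± 51.1 CPM for Glyma.07G243500). Cotyledon counts of Glyma.07G243500, Glyma.17G030400 and Glyma.07G243651 were almost equal (2140, 2137 and 2146), so these genes may share reads.

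Of the photosynthesis list, a marker of green tissue, 37 of 66 members fell and 4 rose (38 and 5 adjusted over the list alone). Among the risen were the PsbP genes Glyma.19G227402 (5.62 ± 0.74) and Glyma.06G014500 (211 against 3 counts, ratio 89.9, interval 30.3 to 439). The list test gave adjusted p = 0.012 at the preset correlation and adjusted p = 0.934 with an estimated correlation. The same pair of values for the chalcone synthase list was adjusted p = 2.2e-07 and adjusted p = 0.934 with an estimated correlation. Of the MYB list, 92 of 314 rose and 61 fell (93 and 61 over the list alone). Of the flavonoid list, 2 of 9 rose and 3 fell (2 and 3 over the list alone), with a chalcone isomerase gene (Glyma.20G241500) higher by 2.63 ± 0.53 and phenylalanine ammonia-lyase 2 (Glyma.20G180800), at the entry of phenylpropanoid synthesis, at −5.24 ± 0.83. Of the RNA silencing list, 7 of 29 rose and 2 fell (7 and 2 over the list alone). The risen included an Argonaute gene (Glyma.02G111600, 267 against 1 counts, ratio 341, interval 60.7 to 13529) and dicer-like 4 (Glyma.17G104100, 84 against 1, ratio 107, interval 18.8 to 4290). Of the auxin list, 12 of 52 rose, among them ARF8 (Glyma.15G091000, 4.35 ± 0.82), and 26 fell (12 and 27 over the list alone). Of the resistance gene list, 40 of 429 rose, among them Glyma.07G063100 (6.43 ± 0.67) and Glyma.02G076850 (4.62 ± 0.60), and 95 fell (35 and 88 over the list alone).

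Both directions also occurred in the seed storage list (28 of 93 rose and 20 fell, and 28 and 20 over the list alone). This list was chosen as a marker of cotyledon and embryo but is of mixed content, so its calls were not read as tissue carried over. Its members with the smallest p, Glyma.10G080102 and Glyma.10G080152 with identical counts (6.25 ± 0.72), are a late embryogenesis hydroxyproline-rich protein gene and an NDR1/HIN1-like gene. Of the laccase and copper protein list, 5 of 43 rose, among them Glyma.01G112600 (7.01 ± 0.87) and the early nodulin-like gene Glyma.17G223400 (5.20 ± 0.67), and 14 fell (5 and 14 over the list alone). Glyma.17G223400 had 4213 counts against 80. The heat shock protein 60 genes Glyma.07G009600 (4202 against 80) and Glyma.08G192700 (4203 against 80) nearly matched it. It may share reads with them, so its rise need not come from a copper protein gene. The remaining lists gave 71 risen and 109 fallen of 384 pentatricopeptide genes (71 and 109 over the list alone), and 19 and 16 of 70 growth factor targets (19 and 16). They also gave 38 and 53 of 162 ribosomal protein genes (41 and 53), 4 and 2 of 23 histone genes (4 and 1) and 29 and 20 of 122 transposon-related genes (29 and 20), none passing the list test. With the stage 2 cotyledon library left out, 20 growth factor targets rose and 29 fell, 8 and 20 laccase and copper protein genes, 9 and 5 RNA silencing genes and 4 and 4 histone genes.

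The groups of 3670 called genes did not overlap, as 25.5% of all tested genes did and 1.67% would by chance for 3 against 7 libraries. The direction of the whole depends on scaling: without TMM factors 6384 genes were higher and 2707 lower and the median gene lay at 0.80 log2 in place of 0.02. No named gene changed direction or lost its call without them. The count was 12812 without the low-count filter, 4634 from antisense hits and 5045 from sense hits.

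**Figure D3:**
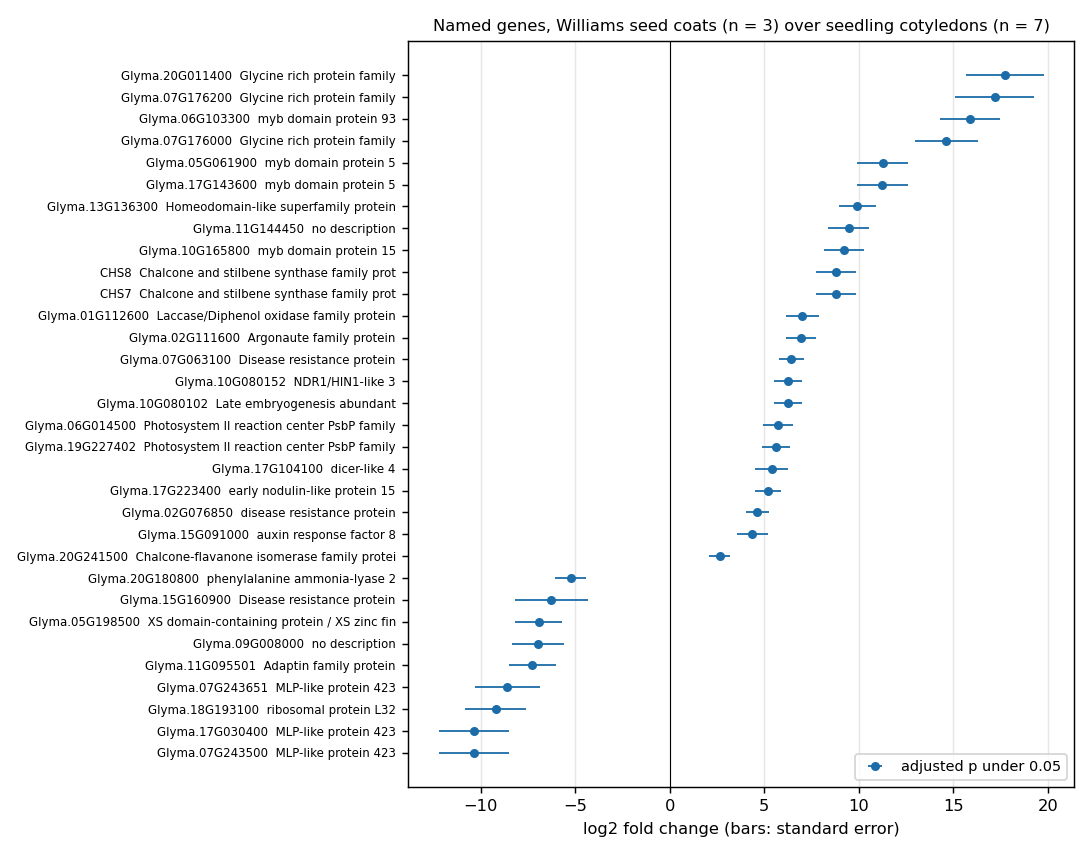
Log2 fold change with its standard error (bars) of the named genes, Williams immature seed coats (n = 3) over seedling cotyledons (n = 7), with adjusted p under 0.05 for each. Glycine-rich protein and MYB genes lie at the top; fitted values for genes with 0 to 3 counts in 1 group, such as MYB93, depend on the prior count.

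Over the 7 seedling cotyledon stages, from stage 1 (imbibed for 48 hr, underground) to stage 7 (fully green), 436 of 12422 genes followed a linear trend, 360 rising and 76 falling. Rising were small RNA hits on genes of photosynthesis: the light-harvesting genes Lhca2 (Glyma.16G016100 and Glyma.07G047600) by 1.34 ± 0.27 log2 per stage, and 12 of 56 photosynthesis list members in all with none lower (29 adjusted over the list alone). The calls over all genes were lost when the stage 2 library was left out: it held 965304 gene hits against 20103525 to 35812799 in the others. Without it no gene passed (0 of 14406 by edgeR, 2981 at unadjusted p under 0.05, smallest adjusted p = 0.0714), and DESeq2 on all 7 called 1461 genes. Without stage 2 the slope was 1.30 for Glyma.16G016100 and Glyma.07G047600, while that of the falling gene Glyma.13G203400 went from −2.16 to −0.21. The median slope without stage 2 was 0.59 in place of 0.74 for the photosynthesis list and 0.64 in place of 0.70 for the chalcone synthase list. It was 0.17 in place of 0.24 for the resistance list, 0.17 in place of 0.25 for the auxin list and 0.09 in place of 0.18 for the transposon list. Adjusted over the list alone, 3 photosynthesis genes then rose and none fell, 79 resistance genes rose and 4 fell, 19 auxin genes rose and none fell, 15 chalcone synthase genes rose and 2 fell, and 6 RNA silencing genes rose and 3 fell. The transposon list no longer passed, and 5 lists passed at the preset correlation in place of 6. With an estimated correlation no list passed the list test without stage 2 (adjusted p = 0.342 for chalcone synthase and 0.409 for photosynthesis). Further rising genes were the O-fucosyltransferase genes Glyma.05G060200 (1.11 ± 0.29) and Glyma.17G142600 (1.14 ± 0.29), a transketolase gene of the Calvin cycle (Glyma.10G293500, 1.16 ± 0.34) and the pentatricopeptide genes Glyma.15G245700 (1.41 ± 0.26) and Glyma.04G221000 (0.99 ± 0.22).

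The named falling genes of the trend drew most of their hits from stage 2 alone. The ADP/ATP carrier gene Glyma.13G203400 (−2.16 ± 0.50) had 354 counts at stage 2 and 3 to 11 at the other stages. The exonuclease gene Glyma.05G163700 (−2.11), actin-related protein 9 (Glyma.20G202700, −1.91), the leucine-rich repeat gene Glyma.08G152800 (−1.87), the U-box kinase gene Glyma.18G147800 (−1.87), the wall-associated kinase genes Glyma.09G027900 and Glyma.15G133400 (−1.86) and a UDP-glycosyltransferase gene (Glyma.08G170200, −1.66) had 247 to 1284 counts there. No chalcone synthase list member passed over all genes (12 of 21 rose adjusted over the list alone): CHS7 was at 0.12 ± 0.16 and CHS8 at 0.13 ± 0.16 per stage, Glyma.08G109500 at 0.70 ± 0.27 and Glyma.19G105100 at 0.53 ± 0.20. The chalcone synthase (adjusted p = 1.9e-09), photosynthesis (7.8e-15), resistance gene (2.9e-06), auxin (3.3e-05) and transposon lists (0.0127) moved up and the growth factor target list moved down (0.0333) at the preset correlation. With an estimated correlation adjusted p was 0.939 for the first 2 and 0.965 for the others.

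Called members of the other lists in the trend were 6 rising of 388 resistance genes (4 over the list alone), among them Glyma.16G182751 (0.90 ± 0.20) and Glyma.01G033300 (1.06 ± 0.25). There were 7 rising and 1 falling of 300 pentatricopeptide genes (7 and 1), 8 and 1 of 240 MYB genes (11 and 1). There followed 2 rising of 22 RNA silencing genes (2), 6 and 2 ribosomal protein genes (9 and 3) and 5 rising of 90 transposon-related genes (7). Of 57 seed storage list members 5 rose (5), among them the late embryogenesis genes Glyma.20G044800 (0.74 ± 0.18) and Glyma.12G194700 (0.86 ± 0.22). The auxin list had 0 of 46 called (2 rising and 1 falling over the list alone; AFB3, Glyma.16G050500, at 0.59 ± 0.20), and none of 6 flavonoid, 55 growth factor target, 36 laccase and 13 histone genes were called either way. The count fell with antisense hits alone, and was 84 without stage 1 (36 rising and 48 falling), 54 without stage 3 (35 and 19) and 208 without stage 6 (184 and 24). Without the low-count filter 359 genes passed, 230 rising and 129 falling, and only 86 of them were shared with the main fit.

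Another CHS gene, Glyma.08G109400, had 1.89 RPM at stage 1, 0 at stage 2, 1.69 at stage 3, 5.71 at stage 4, 7.15 at stage 5, 18.6 at stage 6 and 28.1 at stage 7. It was chosen from the CHS genes after these values were seen, so no test is given, and each stage is 1 library.

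**Figure D4:**
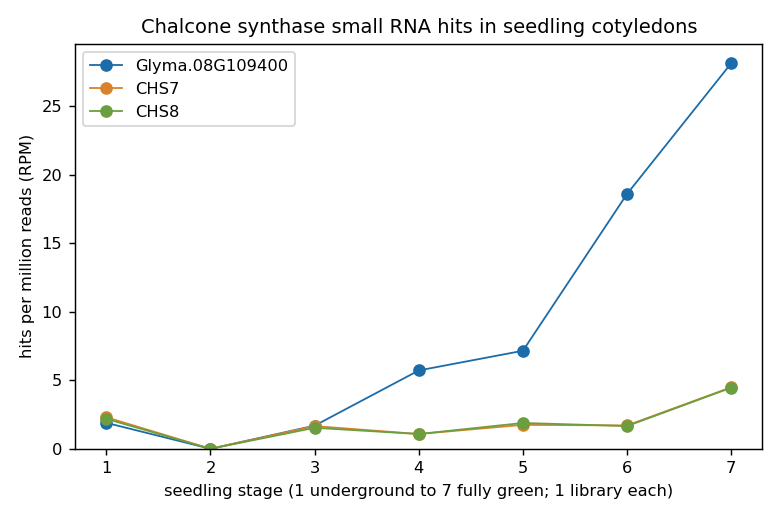
RPM of Glyma.08G109400, CHS7 and CHS8 in the 7 seedling cotyledon libraries against stage, 1 library per point. Glyma.08G109400 reaches 28.1 RPM at stage 7, where CHS7 and CHS8 lie under 5 RPM; all 3 genes have 0 hits at stage 2.

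Vegetative buds and adult shoot tips of the Clark isolines differed for 345 of 14015 genes, 307 higher and 38 lower in buds (3 against 4 libraries, with isoline and the 1-month tips as terms). Antisense hits on many SPL genes, squamosa promoter-binding transcription factors that promote the adult phase and are known targets of miR156, were lower in buds. Of 35 tested genes so described, tallied after the values were seen, 22 fell, none rose and 13 were not called, and the 22 formed 5 groups of near-equal counts, the largest of 16 genes. SPL12 (Glyma.13G274900) fell by 3.11 ± 0.50 log2, and Glyma.06G205701, Glyma.11G163828, Glyma.08G011500, Glyma.11G251500, Glyma.18G005600 and Glyma.01G075800 lay between −2.47 and −2.45, with 98.9 to 100% of their hits antisense (for Glyma.11G251500, 1.10 ± 0.168 CPM in buds and 6.36 ± 1.37 in adult tips). In the other direction, the antisense hits of 2 genes of the HCO3- transporter family, which includes boron exporters, Glyma.19G219500 (5.71 ± 0.41) and Glyma.03G222300 (5.69 ± 0.41), rose from 1.3 to 70.9 CPM on average.

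Higher in buds were also the antisense hits of MYB33 (Glyma.13G073400 at 2.20 ± 0.32 and Glyma.15G225300 at 2.25 ± 0.33), a known miR159 target, and of ARF10 (Glyma.11G145500 and Glyma.12G076200, 1.29 ± 0.28 each), a known miR160 target in auxin signalling. RAD51D (Glyma.11G143900, 4.79 ± 0.94), an aspartyl protease gene (Glyma.19G256400, 3.95 ± 0.88) and a DUF581 gene (Glyma.07G246200, 3.26 ± 0.79) rose too. So did a lectin kinase gene (Glyma.04G139100, 3.12 ± 0.50), a clathrin adaptor gene (Glyma.11G114600, 3.01 ± 0.49) and a mitochondrial transcription termination factor gene (Glyma.05G075600, 2.92 ± 0.56). The acid phosphatase genes Glyma.07G014500 (−3.68 ± 0.65) and Glyma.08G200100 (−3.23 ± 0.67), whose hits were all sense, were lower. CHS7 (0.06 ± 0.39) and CHS8 (0.18 ± 0.42) did not pass, nor did any of the 21 chalcone synthase list members.

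By list, 12 of 70 growth factor targets fell in buds, all 12 of them SPL genes in 3 groups of near-equal counts, and none rose (14 adjusted over the list alone). Of the auxin list 11 of 48 rose, 3 genes of ARF10, 5 of ARF16 and 3 of ARF17, and none fell (13 over the list alone); these 11 had near-equal counts. Of the resistance gene list 16 of 378 rose (24 over the list alone), among them Glyma.06G275000 (1.78 ± 0.26) and Glyma.08G192900 (2.20 ± 0.35), of the MYB list 7 of 272 (7), and of the pentatricopeptide list 5 of 293 (0). The ribosomal protein list had 4 risen (4), among them L35 (Glyma.17G071200, 2.54 ± 0.42) and S2 (Glyma.07G071200, 2.50 ± 0.51). The photosynthesis list had 2 of 59 risen (8), PsbA (Glyma.13G028200, 2.15 ± 0.39) and a PsaA/PsaB gene (Glyma.07G143800, 3.59 ± 0.61), both from sense hits. None of the transposon-related genes was called over all genes, but 27 rose and 1 fell over the list alone, with hAT genes Glyma.06G219500 and Glyma.19G102600 at 1.31 ± 0.33 and 1.30 ± 0.33. No member of the flavonoid (6), RNA silencing (25), laccase (29), seed storage (74) and histone (30) lists was called.

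The growth factor target list (down, adjusted p = 2.2e-05) and the resistance gene (1.6e-06), transposon-related (2.2e-05) and auxin lists (0.00438, all up) passed at the preset correlation; with an estimated correlation adjusted p was 0.207 for the first and 0.74 for the others. The counts rested on single libraries: 7 genes passed without the five-foliate bud and 7 without the adult five-foliate tip, both HCO3- transporter genes among them each time and no SPL gene. The count also fell more than 1.5-fold without standard tip replicate 1, and was 179 without the adult glabrous tip. Without the standard bud 195 genes were higher and 127 lower. Without TMM factors 154 genes passed (123 higher and 31 lower, median of all genes −0.28 in place of −0.14), without the low-count filter 606, and by DESeq2 622.

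**Figure D5:**
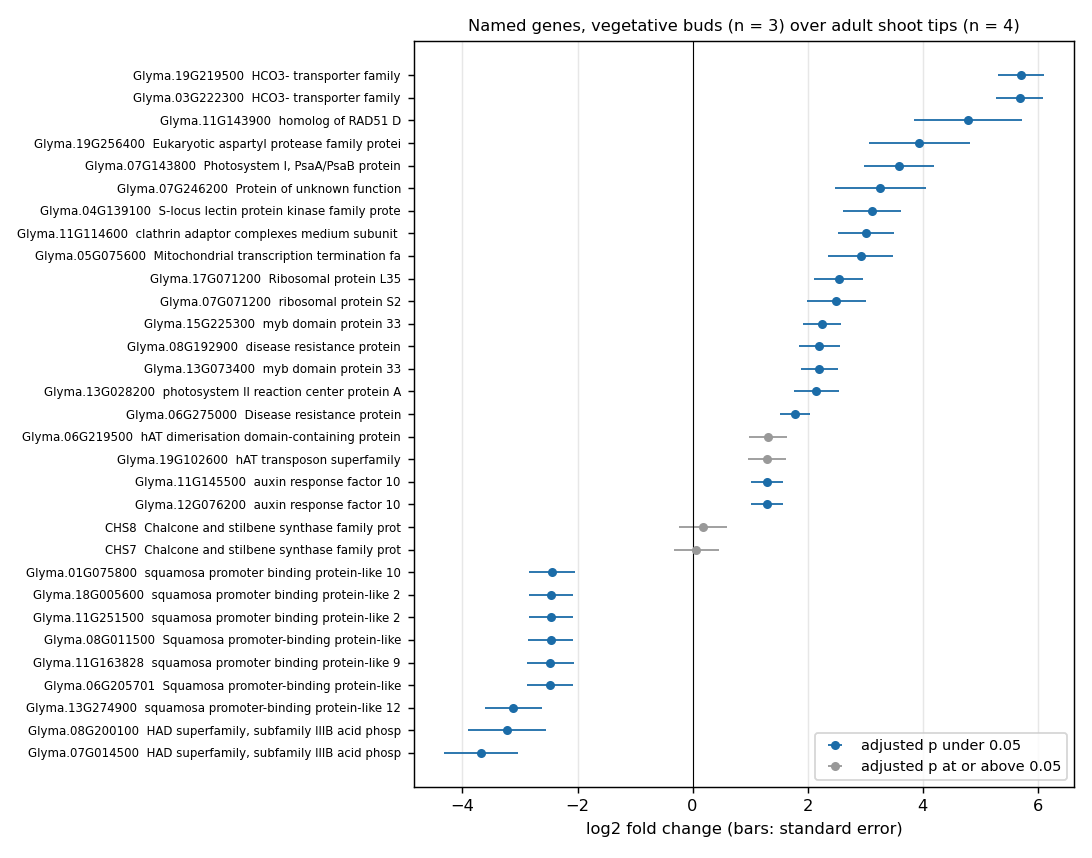
Log2 fold change with its standard error (bars) of the named genes, vegetative buds (n = 3) over adult shoot tips (n = 4), blue with adjusted p under 0.05 and grey at or above it. The SPL genes lie at or under −2.45 and the 2 HCO3- transporter genes at 5.69 and 5.71.

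Between isolines no gene passed. Five-foliate (Lf1) differed from standard Clark in 0 of 14015 genes by edgeR (845 at unadjusted p under 0.05, smallest adjusted p = 0.228; 3 genes by DESeq2, Glyma.03G110600, Glyma.07G028500 and Glyma.10G121000, named after their values were seen). Glabrous (P1) differed in 0 (2404 at unadjusted p under 0.05, smallest adjusted p = 0.141; 16 genes by DESeq2), each with 3 libraries. Among the genes with the smallest p of their lists, not of all genes, were MYB86 (Glyma.05G040700, −5.69 ± 0.97) and MYB55 (Glyma.17G085651, −5.39 ± 0.96) in five-foliate and the resistance gene Glyma.16G137000 (3.16 ± 0.63) and the plantacyanin genes Glyma.04G242300 and Glyma.06G121100 (2.34 ± 0.50) in glabrous. MYB86 and MYB55 rest on few counts: each had 18 in the 3 standard libraries and 12 in five-foliate, all 12 in the 1-month tip, and the 1-month level holds no standard library, so their fitted values are uncertain. ARF10 (Glyma.11G145500 and Glyma.12G076200) was at −1.03 ± 0.32 in glabrous and an Argonaute gene (Glyma.14G041100) at 1.66 ± 0.52. CHS7 was at 0.22 ± 0.44 and 0.05 ± 0.45 and CHS8 at 0.21 ± 0.47 and 0.14 ± 0.48 in five-foliate and glabrous.

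The chalcone synthase (adjusted p = 0.00738), auxin (0.0245) and photosynthesis lists (0.0453) moved down in five-foliate and the auxin list (0.0309) in glabrous at the preset correlation, with adjusted p = 0.49, 0.49, 0.684 and 0.894 with an estimated correlation. Adjusted over the list alone, MYB86 and MYB55 fell and a lipid-transfer protein gene (Glyma.10G121000, 4.32 ± 0.88) rose in five-foliate. Glyma.10G121000 also rests on few counts. It had 12 in the standard bud and 0 in both standard tips. In bud, 1-month tip and adult tip it had 58, 2 and 47 in five-foliate and 54, 1 and 62 in glabrous. Its fitted value in glabrous was alike (3.64 ± 0.88) but not called, so the rise was not particular to five-foliate. In glabrous 10 auxin genes and the ribosomal protein gene Glyma.13G300300 (−3.82) fell and the 2 plantacyanin genes rose. No other list had a call. Without the low-count filter 44 and 20 genes passed in five-foliate and glabrous, and 6 and 12 from the unique hits. Spiked simulated changes of 3 log2 were recovered for 66.7 and 81.2% of genes in these 2 comparisons, and changes of 1 log2 for 1.45 and 0%.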

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

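The tests on Williams 44 strand shares, on read sharing among the genes lower in Richland and on other splits of the libraries were chosen after the results had been seen. In 5 groups of 5 to 9 libraries, 8 measures of depth, composition and CHS level were each screened for a library far from the rest of its group. Of these 40 combinations 8 held such a library, where chance gives about 1 in 20.

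The stage 2 seedling cotyledon library stood apart from the other 6 stages: it had hits on 1122 genes, the fewest of the 7, and its 20 most abundant genes took 92.9% of hits, the most of the 7. Its low number of hits alone, or a random part of its reads, does not account for the few genes, since each of the other 6 libraries, thinned at random to its 965304 hits, still had hits on at least 9965 genes (mean of 20 draws), 8.88 times as many. The threshold for that test was set before its result was seen. A loss of most distinct molecules in library preparation, columns filled from a part of the reads that was not random (0.0484 gene hits per read) and a transient state of stage 2 cotyledons may each explain it; none was tested, and all stay open, as does the meaning of its 0 CHS hits. Without it 0 genes passed in the trend over all genes, while the median slope of photosynthesis genes was 0.59 in place of 0.74 and 5 lists passed at the preset correlation in place of 6. No list passed with an estimated correlation (list test, photosynthesis adjusted p = 0.409).

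The Williams 44 seed coat stood apart from the 4 T157 libraries, the other i seed coats, in its CHS7 and CHS8 sum of 121 RPM and in its 2.06 gene hits per read. Reads carried over from a seed coat library with silencing are argued against by strand: the antisense share of its CHS hits was at most 0.32% (upper 95% counting bound), while the lowest antisense share among the 9 seed coats with I or i-i was 18.3%. General release of fragments from flavonoid messenger RNAs in a pigmented coat stays open. The summed sense RPM of the other flavonoid pathway genes was 0.406 times that of the highest i-i immature seed coat, Clark 63, and a value at or below that coat had been set beforehand as the sign against it. That bound was wrong, since it compared across cultivars and the i-i coats vary widely: the sum was 100 RPM in Williams 44 and 215, 40.8 and 54.2 RPM in Williams replicates 1, 2 and 3, so a rise within the Williams background would not be seen. Fragments of CHS messenger RNA alone remain a candidate explanation too, which was not tested. Stage (50 to 75 mg) and cultivar differ from T157 too and cannot be separated in 1 library.

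The 51 genes lower in Richland than in T157 formed 22 groups of near-equal counts, fewer than any of 200 draws of as many tested but uncalled genes of like abundance (43 to 51 groups), and the 70 higher genes formed 41 groups, against 51 to 66 in such draws. Called genes share a direction over the same libraries, which alone makes their counts more alike than those of uncalled genes. The draws therefore cannot tell how much of the grouping comes from shared reads. Reads shared between genes remain a candidate explanation for the length of both lists. Of the 51, 38 were lower in Richland also at 10 to 25 mg, where 1 library of each line exists, and of the 70 higher genes 63 were higher there, including all 19 of the chalcone synthase list. No biological explanation was tested.

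Other libraries far from their group were the 200 to 300 mg Williams seed coat (replicate 3), with 51.3 M reads (M, 1e+06) and 85.3 M gene hits, the most of the 9 seed coats with I or i-i, and the 1-month glabrous shoot tip, with 58.5 M reads and 51.7 M gene hits, the most of the 6 shoot tips. The dry mature seed coat, outside every comparison, held 5295 RPM of CHS7 and CHS8, against at most 11.5 RPM in the 21 libraries of other i-i tissues.

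Other splits of the same libraries were fitted for each comparison of groups. For Williams seed coat against cotyledon only the real split, 1 of 100 drawn from 120, gave as many as 7908 genes (highest other 2222). Every other split mixes the 2 tissues on at least 1 side, which adds the tissue difference to the spread and lowers its count. The test therefore cannot exclude chance for this count. The highest other split joined Williams seed coat replicates 1 and 2 with the stage 2 cotyledon library. The other comparisons have too few splits for a share under 0.05. For Richland against T157 the real split gave 121 genes and the highest other 16 (1 of 10 splits reached it). For buds against adult tips, with libraries exchanged only within isolines, the real split gave 345 and the highest other 105 (1 of 12). For five-foliate and for glabrous, with libraries exchanged only within tissues, the real count and the highest other were 0 (6 of 6 splits each).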

How the results depend on the processing

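The merging of identical genes, the sum over 20 CHS genes and the list tests without stage 2 were chosen after the data had been seen; the other alternatives were set beforehand. The CHS contrasts kept their direction throughout. With single libraries left out in turn (every library for Richland against T157, each of the smaller group for the other 2), the log2 difference was 4.00 to 4.59 for Richland against T157, 8.94 to 9.81 for i-i seed coats against other tissues and 5.57 to 6.44 for I or i-i against i seed coats, and only the linear scale took the last past the threshold (3070 RPM, exact p = 0.0619). Replicate numbers did not pair Richland with T157, since the correlations of same-numbered libraries (−0.215, −0.152 and −0.162) lay below all the others; a replicate block gave 89 genes, 88 of them shared with the 121, and 4.26 for CHS7 plus CHS8.

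Gene counts moved by over 1.5 times as follows, and the cause was not tested except where fewer hits or more genes entered by construction. With antisense hits alone they were 75 for Richland against T157, 4634 for Williams seed coat against cotyledon and, to 2 digits, 1.7e+02 for the trend; with sense hits alone 66 and 5045 for the first 2; with identical genes merged 75 for the first. Without the low-count filter they were 12812 for seed coat against cotyledon, 606 for buds, 44 for five-foliate and 20 for glabrous. DESeq2 gave 1461 for the trend, 622 for buds, 3 for five-foliate and 16 for glabrous, unique hits 6 and 12 for the isolines, and no TMM factors 154 for buds. Leaving out each library in turn gave 99 to 156 for Richland against T157, 6871 to 9394 for seed coat against cotyledon, 0 to 560 for the trend, 7 to 466 for buds, 0 to 5 for five-foliate and 0 to 4 for glabrous. The 5 genes, without standard tip replicate 2, were Glyma.03G110600, Glyma.03G243800, Glyma.05G040700, Glyma.12G010300 and Glyma.17G085651. The 4 genes, without the standard bud, were Glyma.03G218900, Glyma.10G190400, Glyma.16G221500 and Glyma.20G200300, all named after their values were seen. Medians of all genes without TMM factors were 0.12 in five-foliate and 0.06 in glabrous, in place of −0.02 and −0.12.

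Of 19 list calls at the preset correlation 1 held with an estimated correlation: 1 for Richland against T157, the chalcone synthase list, and 0 for each of the other 5 comparisons. Without stage 2 there were 4 list calls for seed coat against cotyledon in place of 2, and 5 for the trend in place of 6. None of these held with an estimated correlation.

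Over 124 pairs of a named gene and a comparison, 1694 refits kept direction and side of the threshold, 34 gained the call, 24 reversed and the rest lost it. In the trend, with antisense hits Glyma.08G170200 gave 0.0455; with single stages left out it ranged from −2.15 to 0.0215, Glyma.18G147800 from −2.49 to 0.16, Glyma.20G202700 from −2.19 to 0.15, CHS7 from −0.0703 to 0.37 and CHS8 from −0.0467 to 0.39, the positive ends of the first 3 without stage 2 and the negative ends of CHS7 and CHS8 without stage 7. In buds CHS7 gave −0.00834 with RLE factors, −0.0614 without TMM factors, −0.0115 with DESeq2 and −0.50 with antisense hits. With single libraries left out it ranged from −0.17 to 0.52 and CHS8 from −0.20 to 0.57, both lowest without the five-foliate bud. In five-foliate CHS8 gave −0.33 with antisense hits and ranged from −0.24 to 0.40, CHS7 from −0.0688 to 0.40, lowest without the five-foliate bud. In glabrous CHS7 gave −0.62 and CHS8 −1.45 with antisense hits and they ranged from −0.17 to 0.56 (lowest without glabrous tip replicate 1) and from −0.0851 to 0.54 (lowest without the standard bud). CHS7 and CHS8 were called in none of these comparisons.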

Other observations

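No tests were run for this part, and its genes were chosen only after the values had been seen. Hits on the squamosa promoter binding protein-like 2 gene Glyma.11G251500 spanned the tissues widely: 3616 RPM in immature cotyledon, 2803 RPM in dry cotyledon and 2449 RPM in dry seed coat (n = 1 each), 267 ± 154 RPM in seedling cotyledons (mean ± SD, n = 7), 82.6 ± 105.5 RPM in immature seed coats (n = 14), 8.19 ± 3.45 RPM in shoot tips (n = 6), 2.85 RPM in leaf (n = 1) and 0.907 ± 0.429 RPM in vegetative buds (n = 3), with at least 98.9% of hits antisense in each. MYB33 (Glyma.15G225300) hits were 1602 ± 615 RPM in embryo axes (n = 2), 1953 RPM in dry cotyledon, 290 ± 201 RPM in immature seed coats and 51.7 RPM in shoot tips (mean, lowest 14.4). Hits on the HCO3- transporter gene Glyma.03G222300 were 56.8 ± 29.9 RPM in buds, 45.8 RPM in dry seed coat, 16.4 ± 6.83 RPM in embryo axes and 0.25 ± 0.173 RPM in seedling cotyledons.

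Sense hits on genes abundant in Williams immature seed coats also marked the dry Williams seed coat. MYB93 (Glyma.06G103300) had 371 RPM and the glycine-rich protein gene Glyma.20G011400 3469 RPM there. Both had 0 hits in seedling cotyledons, buds and shoot tips. Among all immature seed coats (n = 14), nearly all hits came from the Williams (i-i) libraries. These held 199772 of 199773 hits on Glyma.20G011400 and 46730 of 46861 on MYB93. Immature seed coats of the other lines were thus nearly without hits on both genes. The Williams coats came from seeds of 100 to 500 mg and those of the other lines from seeds of at most 100 mg. Line and seed weight therefore cannot be told apart here. In dry cotyledon the glycine-rich gene had 4.04 RPM and in embryo axes 4.80 ± 2.15 RPM.

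The ratio of CHS7 hits to hits on the chromosome 8 gene Glyma.08G109400 was 2.18 to 5.17 (mean 3.00) in the 5 i-i immature seed coats and 0.772 to 1.29 (mean 0.936) in the 4 I seed coats. It was 4.41 in the dry seed coat, 3.26 in Williams 44 and 0.508 to 1.21 in T157. No test is given, since gene and ratio were chosen after the values were seen, and all I libraries are Richland seeds of at most 25 mg while all i-i libraries are Williams or Clark seeds of at least 50 mg.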
